A study of Caenorhabditis elegans with 4 samples.

How the data were processed

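Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole third-stage (L3) larvae of the wild-type Caenorhabditis elegans strain N2, grown at 20 degrees Celsius. The labels describe the population as males and hermaphrodites together. They give 4 samples in 2 groups of 2. One group is the ZFP-1 immunoprecipitate, replicates 1 and 2, and the other is the input DNA, replicates 1 and 2. Per the labels' protocols, each immunoprecipitation used 2 mg of extract with 1% sarkosyl, and 10% of it was set aside as input. The antibody was an affinity-purified rabbit polyclonal raised against amino acids 573 to 867 of ZFP-1. The labels do not say whether the replicates came from separate cultures, so the spread between them may be technical.

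The data used are 3 peak lists in GFF3 format, which the authors deposited as start, end and 1 score per peak. One list belongs to each ChIP replicate, and their caller is written as MACS per the file contents. The third belongs to the whole series and its caller is written as MACS v2. Whether the series list was called on pooled reads is not stated in the sources used here, nor is the use of the input as control. Coordinates are on WormBase WS220, per the file headers, and are 1-based with both ends included. The submitters' processing notes name BWA and the build ce10, without giving roles. The score that the authors deposited has no stated scale. In the replicate lists it started just above 50 and many peaks were tied at exactly 3100, so it was used to rank and filter peaks within 1 list and, between the 2 replicate lists, for a correlation of log10 scores over shared peaks. Input libraries had no peak list analysed here, so no input background could be set beside the values.

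No read counts were used, so the depth of each library is unknown and no interval that needs it was computed. Intervals on shares of peaks are exact Clopper-Pearson 95% intervals. They cover counting error over peaks only, not error between animals or libraries, and they treat neighbouring peaks as independent.

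Peak counts, overlaps and densities were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Overlap counts were checked against bedtools 2.31.1 and were equal in every pairing of the 3 lists. Peaks of separate lists were counted as shared from 1 bp of overlap. Chance overlap was measured with 100 seeded random placements of one list, which kept every peak's width and chromosome and let no peaks overlap. Chromosome lengths were taken as the last base covered by any peak of the 3 lists, which is a lower limit of the true length. The X chromosome was compared with the 5 autosomes by an exact two-sided binomial test of peak counts against the share of sequence. Because neighbouring peaks are not independent, 500 kb bins of X and of the autosomes were also compared by a two-sided permutation test with 100000 resamples, both for their number of peaks and for the share of better-scoring peaks in each bin, and again within the chromosome centres. The central part of each autosome was its middle 33.3% by position of peak midpoints. It was tested by an exact two-sided binomial test, and again with 2000 random rotations of the positions on each chromosome, which keep the spacing of peaks. Benjamini-Hochberg adjustment was applied over the 6 binomial tests (X and centre in 3 lists).

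Scripts were tested on simulated data. In 20 simulated series lists of 13878 peaks built with an X to autosome density ratio of 1.5, the mean ratio found was 1.49, and the interval held 1.5 in 19 of them. In lists built with 50% of autosomal peaks in the central part, 50.0% were found there on average. In a further check, part of the 3559 replicate 1 peaks was copied with a small shift into a second list and the others were placed at random. Of the copies, 100% were found. Simulated series-list peaks were independent of each other, so their intervals say nothing of real peaks that lie close together. Copies shifted by less than a peak width must overlap, so the last check tested the code only.

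Gene-based comparisons had been planned: the share of peaks at transcript starts, the share of genes with a peak on X and autosomes, closely spaced starts, and 26 gene lists. The gene table used here is on assembly WBcel235, which is another build than the peak files, and coordinates of separate builds were not mixed. Peaks were therefore assigned to no gene and are named by position. The rule for named peaks, fixed before the data were examined, was the 20 series-list peaks with the highest score that overlapped a peak in both replicates. Alternatives were the overlap criterion, the score threshold, the list used, lists of equal length, ranks in place of scores and a wider centre, and several more were added after seeing the data.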

Results

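ZFP-1 is a nuclear zinc-finger protein of C. elegans, related to mammalian MLLT10, that acts together with the histone methyltransferase DOT-1.1. Its binding sites were mapped by ChIP-seq in wild-type L3 larvae, so the design asks where on the chromosomes ZFP-1 was bound at this stage. The data held 1 ChIP group of 2 replicates and no second stage or genotype. Comparisons were therefore made between the replicates, between each replicate and the series list, and between chromosomes and chromosome parts within each list.

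Replicate 1 listed 3559 peaks and replicate 2 listed 6371 peaks. The series list held 13878 peaks. Peaks in the replicate lists were broad, with a median width of 1268 bp in replicate 1 (interquartile range 1039 to 1919 bp) and 1200 bp in replicate 2 (990 to 1861 bp). Series-list peaks had a median width of 331 bp (227 to 510 bp). Peaks covered 6.05 Mb in replicate 1, 10.95 Mb in replicate 2 and 6.08 Mb in the series list, which is 6.04%, 10.9% and 6.06% of the span of chromosomes I to V and X. The median score was 205 in replicate 1, 352 in replicate 2 and 16.9 in the series list. These scores are the authors' own per peak. The files name the caller as MACS v2 for the series list and MACS for the replicate lists, so scores of the series list were not set against those of the replicates. A score of 3100 or more was reached by 96 peaks of replicate 1 and 521 of replicate 2. Depth was unknown.

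Most replicate 1 peaks touched a replicate 2 peak: 3479 of 3559, or 97.8% (95% interval 97.2 to 98.2%), overlapped one by at least 1 bp. In the other direction, 3211 of 6371 replicate 2 peaks, or 50.4% (49.2 to 51.6%), overlapped a replicate 1 peak. Shared bases made up 49.1% of the bases covered by either list. Random placement of replicate 2 peaks on the same chromosomes gave on average 22.02% for the first share, with a highest value of 23.6%, and 11.9% for the second, with a highest value of 12.7%. For either share, 0 of 100 placements came as high. With a reciprocal overlap of 50%, the shares were 77.9% and 43.5%, against 5.48% and 3.06% on average by placement. The 80 replicate 1 peaks with no counterpart had a median score of 69.7, against 216 for those with one. The 3160 replicate 2 peaks with no counterpart had a median score of 138, against 1121 for those with one.

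Recovery in replicate 1 rose with the replicate 2 score. Of the lowest-scoring 20% of replicate 2 peaks, 8.71% (7.22 to 10.4%) met a replicate 1 peak, then 18.8%, 43.2% and 81.5% in the next 20% steps. Of the highest-scoring 20%, 99.7% did (99.2 to 99.9%, 1271 of 1275 peaks). Random placement gave 11.9% on average for replicate 2 peaks of all scores and widths. That placement moved the whole list and kept no strong peak in position, so it sets no chance level for the lowest-scoring 20%. Whether their overlap exceeds chance was not tested. Over the 3165 pairs of peaks that were each other's best overlap, the log10 scores of the replicates correlated with Pearson r = 0.74 and Spearman rho = 0.80. This correlation is across peaks, which are not independent replicates, and tied scores at 3100 enter it. With pairs at 3100 or above in either list left out, 2644 pairs gave r = 0.66. Counts of peaks in 197 bins of 500 kb correlated between replicates with r = 0.89 and rho = 0.90, again across positions and not across samples. Within the 35 bins of X, r was 0.80 and rho was 0.70.

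The series list held nearly every site of the replicates: 3550 of the 3559 replicate 1 peaks (99.7%) and 6360 of the 6371 replicate 2 peaks (99.8%) overlapped one of its peaks. Of the 13878 series-list peaks, 5334 (38.4%, 37.6 to 39.3%) met a peak in both replicates and 4907 (35.4%, 34.6 to 36.2%) met replicate 2 alone. A further 131 (0.94%, 0.79 to 1.12%) met replicate 1 alone, and 3506 (25.3%, 24.5 to 25.99%) met neither. The series holds 2 ChIP libraries, so the series list is not a measurement independent of the replicate lists. Peaks met in both replicates had a median series score of 57.0 and a median width of 533 bp. Peaks met in replicate 2 alone had a median score of 17.3 and a width of 326 bp, and peaks met in neither had a median score of 7.04 and a width of 205 bp. A replicate peak often held several series-list peaks. Of the replicate 2 peaks, 32.3% held 2 or more, and those with any held a mean of 1.61 and a maximum of 15. With a reciprocal overlap of 50%, which narrow peaks inside wide ones fail, the share met in both fell to 4.41%.

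**Figure D1:**
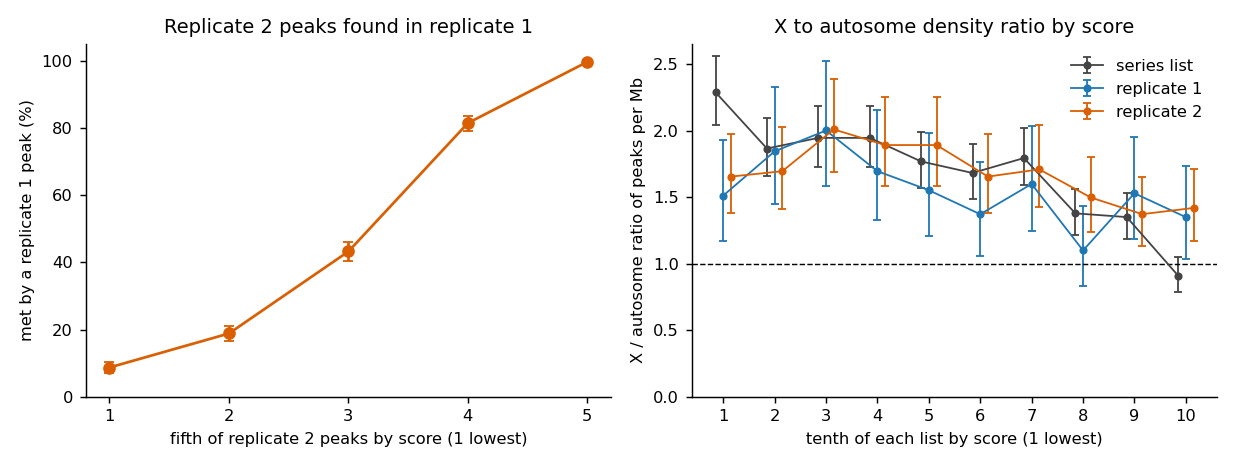
Left, share of replicate 2 peaks that overlap a replicate 1 peak (%), in 5 equal parts of the replicate 2 score. Right, ratio of X to autosome peaks per Mb in 10 equal parts of each list's score, for the series list and each replicate. Bars are exact 95% binomial intervals. The share on the left rises from 8.71% to 99.7%, and the series-list ratio on the right goes from 2.29 in the lowest part to 0.91 in the highest.

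The 20 highest-scoring series-list peaks with a counterpart in both replicates lay on all 6 chromosomes, with 4 on I, 5 on II, 2 on III, 2 on IV, 5 on V and 2 on X. Their series scores ran from 217.98 to 227.99 and their widths from 480 to 2135 bp. The first 3 shared the score of 227.99. They were II from 13640992 to 13641775, III from 13001931 to 13002632 and X from 11974191 to 11975179. The site on II from 3896676 to 3897404 and the one on V from 6996925 to 6999059 both scored 227.85. The site on IV from 7817457 to 7818473 scored 226.84. It was followed by II from 12102244 to 12102723 at 226.47, IV from 12842757 to 12843441 at 225.78, and V from 531953 to 532541 and X from 7129320 to 7130140, both at 223.56. On chromosome I the leading sites were from 8786527 to 8787471, from 39595 to 40604, from 1540432 to 1541095 and from 7541961 to 7542692, with scores of 220.91, 220.23, 220.23 and 218.70. The remaining sites of the 20 were on V from 13952548 to 13953509, from 1150799 to 1152159 and from 11921168 to 11922544, on II from 8484307 to 8484979 and from 602970 to 603464, and on III from 9949499 to 9951428. In replicate 2, 18 of the 20 lay under one of its highest-scoring 10% of peaks. In replicate 1, 10 of the 20 did, and the replicate 1 scores of all 20 ran from 582 to 3100. All positions are on WS220, and no gene was assigned to them.

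The widest peak of each replicate lay on chromosome II, from 6823978 to 6837641 in replicate 1 (13664 bp) and from 6820012 to 6848837 in replicate 2 (28826 bp). The second widest lay on X, from 11471325 to 11484877 in replicate 1 (13553 bp) and from 11461194 to 11485259 in replicate 2 (24066 bp). The series list divided the replicate 2 region on II into 14 peaks covering 24418 bp, and replicate 1 divided it into 6 peaks covering 27302 bp. Of the 10 widest peaks of replicate 1, 5 overlapped one of the 10 widest of replicate 2, against at most 1 in 100 random placements. The widest series-list peak, on I from 15061279 to 15068324 (7046 bp, score 15.5), met replicate 2 alone. It lay inside the replicate 2 peak from 15059917 to 15071786, at the right end of I where the ribosomal RNA genes form a tandem array. No input background could be set beside it, so it is not shown to be a broad ZFP-1 site.

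**Figure D2:**
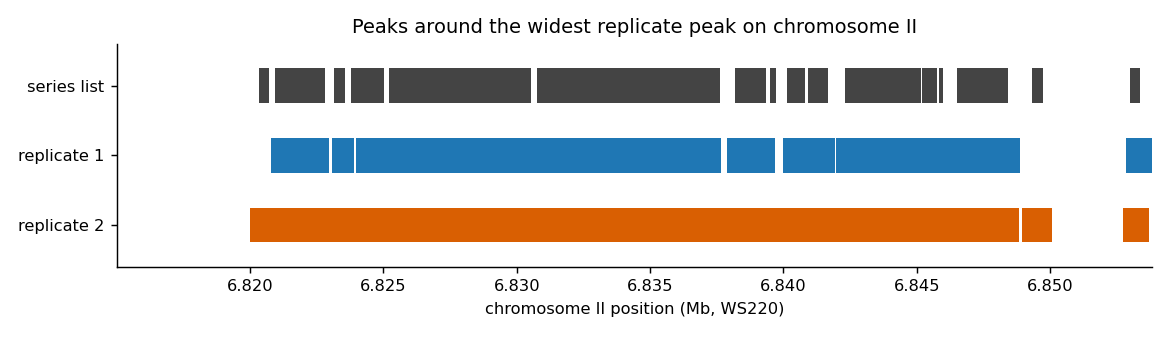
Peaks of the 3 lists on chromosome II around the widest replicate peak, to scale, with position in Mb (WS220) on the x axis and 1 row per list. Each bar is 1 peak; replicate 2 has a single peak of 28826 bp where replicate 1 has 6 peaks and the series list has 14.

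The X chromosome differs in this species from the autosomes in dosage compensation and in germline expression. It carried the highest density of ZFP-1 peaks in all 3 lists. Both replicates placed X first, and the series list is not independent of them. The series list held 207 peaks per Mb on X and 124 per Mb on the autosomes, a ratio of 1.67 (95% interval 1.61 to 1.74). The ratio was 1.55 (1.43 to 1.67) in replicate 1, at 50.1 against 32.4 peaks per Mb, and 1.67 (1.58 to 1.77) in replicate 2, at 95.1 against 56.8. X held 3664 of the 13878 series-list peaks, or 26.4%, on 17.7% of the span. The covered share of X was 9.29% in the series list, against 5.37% of the autosomes, a ratio of 1.73. The covered-base ratio was 1.62 in replicate 1 and 1.77 in replicate 2. The exact binomial tests gave adjusted p-values of 3.7e-143, 2.96e-27 and 4.25e-67 for the series list, replicate 1 and replicate 2, over 6 tests, but they treat peaks as independent. With 500 kb bins as units, X bins held 103 ± 21.2 series-list peaks (SD, 35 bins) and autosomal bins 61.8 ± 29.1 (SD, 162 bins). The permutation test gave p = 2e-05 in each list, the smallest that 100000 resamples can give. Neighbouring bins are not independent either, and with whole chromosomes as units X ranked first of 6, for which an exact permutation cannot go below 0.167.

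Among the autosomes, the order was similar in the 3 lists. III and I were the densest, with 150 and 141 series-list peaks per Mb, and V was the sparsest with 97.7. The mean over the 5 autosomes was 127 ± 20.7 peaks per Mb (SD, 5 chromosomes) in the series list, 33.1 ± 6.03 in replicate 1 and 58.1 ± 9.64 in replicate 2. X lay above the densest autosome in each list: 207 against 150, 50.1 against 39.3, and 95.1 against 68.7 peaks per Mb.

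**Figure D3:**
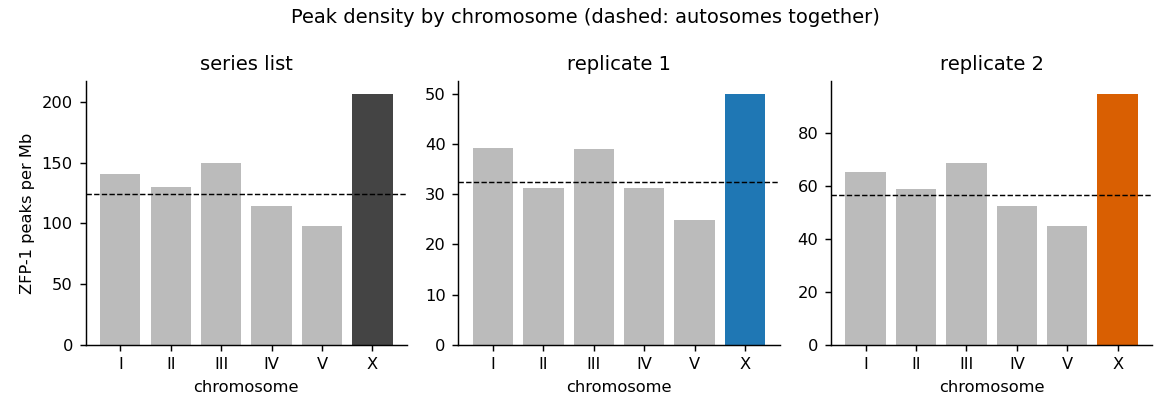
ZFP-1 peaks per Mb (y axis) on each chromosome (x axis) in the series list and in each replicate, with the 5 autosomes in grey and X in colour. The dashed line is the density of the autosomes together; X stands at 207, 50.1 and 95.1 peaks per Mb, above every autosome in its list.

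The excess on X was smaller among the better-scoring peaks of the series list. There, X held 29.7% of the lower-scoring 50% of peaks and 23.1% of the better-scoring 50% (two-sided Fisher's exact test, adjusted p = 5.33e-18 over 6 tests). It held 16.35% of the highest-scoring 10%, where the density ratio was 0.91 (0.79 to 1.05) and did not differ from 1 (exact binomial test, p = 0.205). The replicates also had a smaller X share in the better-scoring 50%, at 22.9% against 26.9% in replicate 1 (Fisher's exact test, adjusted p = 0.00891) and 24.7% against 28.2% in replicate 2 (adjusted p = 0.00355). Fisher's test treats peaks as independent. With 500 kb bins as units, the better-scoring 50% made up 44.6 ± 6.23% of the series-list peaks on X (SD, 36 bins) and 53.8 ± 8.57% on the autosomes (SD, 167 bins), with a permutation test p of 6e-05 after adjustment over 6 tests. The shares were 46.8% on X and 51.7% on the autosomes in replicate 2, which passed the same permutation test (adjusted p = 0.0244). They were 46.3% and 50.9% in replicate 1, which did not (permutation test, adjusted p = 0.154). In their highest-scoring 10%, the ratio was still 1.35 (1.04 to 1.74) in replicate 1 and 1.42 (1.17 to 1.71) in replicate 2. The X share of those peaks was not shown to differ from the rest of each list (Fisher's exact test, adjusted p = 0.273 and 0.078). Support in the replicates did not follow the same order: the X ratio was 1.62 (1.52 to 1.72) for series-list peaks met in both replicates, 1.93 (1.81 to 2.05) for those met in replicate 2 alone and 1.44 (1.33 to 1.55) for those met in neither, the class with the lowest median score.

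On the autosomes, ZFP-1 peaks were concentrated towards the chromosome centres, which in C. elegans are gene-dense while the arms are richer in repeats. The central 33.3% of the autosomes held 45.7% of the autosomal series-list peaks (44.7 to 46.7%), 43.0% in replicate 1 (41.1 to 44.9%) and 42.0% in replicate 2 (40.6 to 43.5%). Density was 170 peaks per Mb in the centres and 100.9 in the outer parts in the series list, a ratio of 1.68. The ratio was 1.51 in replicate 1 and 1.45 in replicate 2. Among the autosomes of the series list, V had the highest central share, 49.7%, and III the lowest, 40.8%. In replicate 2 the share on III was 35.9% (32.9 to 39.1%), not shown to differ from 33.3% (exact binomial test, p = 0.091). Of the outer and central parts of all chromosomes, the right part of V was the sparsest in each list, with 59.4 series-list peaks per Mb against 146 in its centre. The exact binomial tests gave adjusted p-values of 1.68e-146, 3.07e-25 and 3.94e-35. Under the rotation permutation test, which keeps the spacing of peaks, the autosomes together gave p = 0.001, 0.0035 and 0.0015 (2000 rotations, two-sided). Taken 1 at a time, no chromosome passed the rotation test after adjustment over 6 chromosomes; the lowest adjusted p was 0.06, for I in replicate 2.

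The central share was lower on X. Its central 33.3% held 33.8% of its series-list peaks (32.3 to 35.3%), 34.0% in replicate 1 (30.9 to 37.3%) and 33.4% in replicate 2 (31.2 to 35.7%). Density on X was 210 peaks per Mb in the centre and 205 outside it. The central 50% of X held 52.4% of its series-list peaks (50.742 to 54.003%, exact binomial p = 0.00426), against 66.2% on the autosomes. That test treats peaks as independent, so a small excess on X is not shown. For the central 33.3%, the rotation permutation test gave p = 0.80 for X in the series list. The central share was lower on X than on the autosomes by 11.9 percentage points in the series list, 8.95 in replicate 1 and 8.60 in replicate 2, and the rotation permutation test gave p = 0.009, 0.0385 and 0.013 for these differences. X was the lowest of the 6 chromosomes in all 3 lists, though in replicate 2 chromosome III came close, with 35.9%. The centre of X was also denser than the autosomal centres, with a ratio of 1.24 (1.16 to 1.32) in the series list, 1.22 (1.07 to 1.39) in replicate 1 and 1.33 (1.21 to 1.46) in replicate 2. These intervals treat peaks as independent. With 500 kb bins of the centres as units, the permutation test gave adjusted p = 0.0191, 0.0903 and 0.00072 for peak counts over 9 tests, so replicate 1 did not pass. With peaks under 5 kb apart merged, no difference between the centres was seen in clusters per Mb. The ratio was 1.02 (0.90 to 1.15) in the series list, 1.12 (0.95 to 1.32) in replicate 1 and 1.07 (0.93 to 1.23) in replicate 2. Merging joins more peaks where they are denser, which itself lowers the ratio, so these values cannot show equal density.

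**Figure D4:**
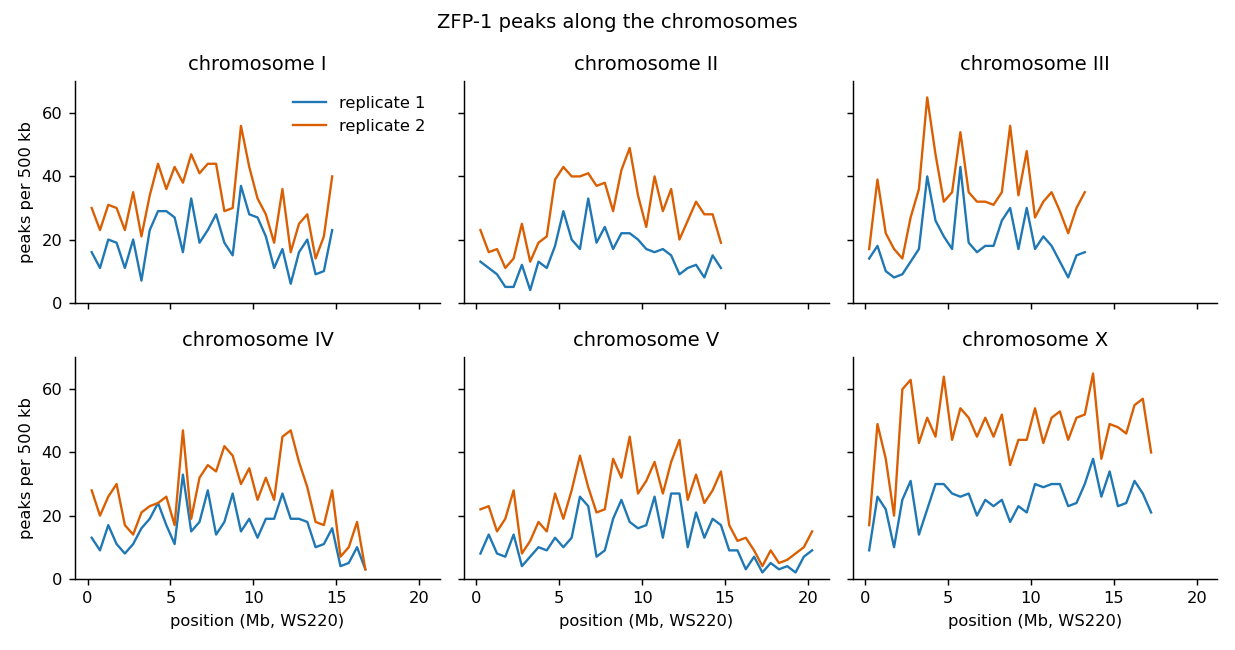
Number of ZFP-1 peaks per 500 kb bin (y axis) along each chromosome (x axis, Mb on WS220) in replicates 1 and 2. Counts are low on the right of IV and of V in both replicates, while counts on X stay high along most of its length.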

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

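Over 15 results and 49 alternatives, 28 alternatives kept the direction and the side of the threshold or stayed within the interval, 19 moved a value without a test beyond its interval, 1 was weaker and 1 changed direction. The direction changed for the X to autosome ratio, from 1.67 to 0.91 (exact binomial p = 0.205) in the highest-scoring 10% of the series list, a threshold chosen after seeing the data, as were merging, covered bases, central parts, leaving out chromosomes and leaving out tied scores. Each replicate's own list in place of the series list gave X ratios from 1.55 to 1.67 and autosomal central shares from 42.0% to 43.0%. Merging peaks under 5 kb apart lowered the X ratio to 1.19. With the centres alone compared it was 1.02 (exact binomial p = 0.774), not shown to differ from 1. Merging itself lowers the ratio where X is denser, so the value of 1.02 does not show equal density. The overlap of 97.8% and 50.4% between replicates became 77.9% and 43.5% with 50% reciprocal overlap. The score correlation of 0.74 became 0.76 with 50% reciprocal overlap, 0.80 on ranks and 0.66 without the tied scores at 3100. The series-list share met in both replicates, 38.4%, became 37.2% with 50% of the shorter peak covered, 4.41% with 50% reciprocal overlap and 34.2% between the better-scoring parts of the lists. Keeping only the better-scoring part of each list raised the median scores, by construction, to 48.8, 590 and 1151 in the series list, replicate 1 and replicate 2. In the same order, the median widths rose as well, to 474, 1536 and 1639 bp. With equal numbers of best-scoring peaks, 86.5% of replicate 1 peaks met replicate 2 and 78.1% the reverse. No paired analysis was possible because the input samples have no peak list analysed here and the 2 ChIP samples form 1 group. The alternatives on promoter windows, transcript starts and gene lists, and placement within promoters, were not run, since no gene was assigned. Depth is unknown, so peaks listed in replicate 2 alone are not shown to be absent from replicate 1.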

Other observations

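ZFP-1 peaks lay close together. In the series list, 39.8% of the gaps between neighbouring peaks were under 1 kb, against 14.6% on average and at most 15.3% in 100 random placements. The share was 44.1% on X (20.3% by placement) and 38.3% on the autosomes (12.57%). Some of these short gaps lay inside a single replicate 2 peak, as 32.3% of replicate 2 peaks held 2 or more series-list peaks. Placement was uniform along each chromosome and did not keep the denser autosomal centres. Shares were lower in the replicate lists, at 15.9% in replicate 1 (3.91% by placement) and 23.03% in replicate 2 (7.47%). On X and on the autosomes the shares were 26.7% and 21.7% in replicate 2 (10.8% and 6.25% by placement) and 14.9% and 16.24% in replicate 1 (5.39% and 3.41% by placement). Placement alone therefore gives a higher share on X, whose peak density is higher, and in none of the 3 lists did X exceed its placement value by a larger factor than the autosomes did. The median gap in the series list was 1308 bp on X and 1976 bp on the autosomes. The densest 100 kb window of the series list was on X from 10600001 to 10700000, with 48 peaks, followed by III from 5900001 to 6000000 with 43 and II from 7600001 to 7700000 with 40. Of 999 such windows, 15 held no peak in any of the 3 lists, and 1 of these was on X. The longest gap of the series list was 221 kb, on I from 13066103 to 13287093.

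Chromosome ends differed between the lists. In replicate 1 the first peak began at base 1 or 2 on all 6 chromosomes, and in replicate 2 on 3 of them (I, II and X). In the series list it did so on I, V and X. The right ends did not follow: the last replicate 1 peak ended before the last replicate 2 peak on all 6 chromosomes. No cause of these differences was tested, so they are not shown to be differences in ZFP-1 binding. The replicate 1 peaks on III from 2 to 714 (score 100.97), on IV from 2 to 799 (score 105.29) and on V from 2 to 876 (score 72.2) had no replicate 2 peak that began before base 14380, 49476 and 7801. At the right end of I, where the ribosomal RNA genes lie in a tandem array, replicate 2 had a peak from 15059917 to 15071786 (11870 bp, score 805). The last replicate 1 peak on I ended at 15042460. These sites were chosen after their values were seen.

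Among the tests of explanations that follow, those of merging, of chromosome arms, of the calling threshold and of the score scale were chosen after the results were seen. The first pattern is the density of peaks on X. If enriched stretches on X had only been split into more pieces, merging peaks under 5 kb apart should remove the excess. The ratio of clusters per Mb was 1.19 (1.104 to 1.28), below the 1.67 of single peaks, and clusters held 4.11 peaks on X and 2.92 on the autosomes, so the excess was smaller with close peaks counted once, but splitting does not account for all of it. A denser chromosome also merges more, and the covered-base ratio was 1.73. Peak-poor autosomal arms are argued against as the whole cause by the ratio of 1.24 in the centres, whose interval treats peaks as independent. With 500 kb bins, the central excess passed in the series list (permutation p = 0.00636) and in replicate 2. It did not pass in replicate 1 (permutation p = 0.0602). The series list is not independent of the replicates, so only 1 of the 2 replicates passed. Splitting and poor arms together stay open. Clusters in the centres gave a ratio of 1.02 (0.90 to 1.15), and 2 autosomes exceeded X. Merging lowers the ratio of a denser X in any case, so these clusters cannot decide. Covered bases in the same central bins of the series list still had a ratio of 1.29 (permutation p = 0.00928). The ratio was 1.32 in replicate 2 (permutation p = 0.00204) and 1.25 in replicate 1, which did not pass (permutation p = 0.0536). The permutation p-values of central bins in this paragraph are before adjustment. Peaks near the threshold are argued against, as the whole cause, by ratios from 1.39 to 1.53 in the better-scoring 50% of the 3 lists. In the series list the ratio was 2.29 in the lowest-scoring 10% and 0.91 (0.79 to 1.05) in the highest, so its strongest peaks show no excess on X. Read mappability and the input on X stay open and were not tested, and no biological explanation was tested because the series holds 1 stage and 1 genotype.

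The second pattern is the fall of the X ratio with score. X peaks were not narrower than autosomal ones (median 343 and 327 bp in the series list), and among the 20% of peaks in the middle by width (285 to 388 bp) the ratio went from 2.54 (2.13 to 3.03) in the lowest-scoring 20% to 0.80 (0.62 to 1.01) in the highest, which argues against width. In the same middle 20% by width of replicate 2 it went from 2.78 (2.14 to 3.61) to 0.82 (0.56 to 1.16), and in replicate 1 from 2.61 (1.82 to 3.72) to 1.397 (0.92 to 2.08), where the intervals overlap. Whether the fall comes from the series list's own score scale stays open. The better-scoring 50% held a smaller X share in both replicate lists (larger Fisher's exact p = 0.00594), but that test treats clustered peaks as independent, and with 500 kb bins as units the difference passed in replicate 2 (permutation p = 0.0122) and not in replicate 1 (permutation p = 0.103). Series-list peaks met in neither replicate, which had the lowest scores, had an X ratio of 1.44, below the 1.62 of peaks met in both. Replicate peaks cover more of X than of the autosomes, which by itself takes X peaks out of the first class. This order therefore decides nothing about the score scale. A candidate explanation, noticed in these data, is that X carries many ZFP-1 regions that are as wide as autosomal ones but weaker; signal tracks over X and autosomes would test it, and a lower signal from all of X may give the same order of scores.

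The third pattern is the near inclusion of the replicate 1 list in that of replicate 2, counted from 1 bp of overlap. If replicate 1 only had less power to call peaks, strong replicate 2 peaks should be recovered and weak ones lost. Of the highest-scoring 20% of replicate 2 peaks 99.7% met a replicate 1 peak and of the lowest 8.71% did, as this predicts. Lower power in replicate 1 is thus a possible explanation. The 11.9% that random placement gave was for all replicate 2 peaks together and sets no chance level for the weak ones. Whether those weak peaks were missed in replicate 1 or were not reproducible calls cannot be told apart. Read depth, immunoprecipitation efficiency and a difference between the worm samples cannot be separated with peak lists.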
